A study of Drosophila melanogaster with 4 samples.

How the data were processed

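Dissociated wing discs of wandering larvae were sequenced as single cells in 4 libraries, 2 of Mef2-GAL4 with an mCherry hairpin (control) and 2 of Mef2-GAL4 with an Argk1 hairpin, both hairpins inserted at the same genomic landing site per the labels. The labels also say that the pouch was removed. About 10000 cells per sample were loaded in experiment 1 and about 20000 in experiment 2, with different versions of the 3′ kit. The deposited matrices hold UMI counts per feature and barcode, made by the authors with Cell Ranger 7.1.0 per the submitters' processing notes; the values are whole numbers with no normalization. The deposited annotation gives a myoblast state for 11489 barcodes; Seurat is named in the submitters' processing notes, and its version and cell limits, the genome build and the annotation release are not given in the sources used here. The series text says that the annotation was replaced by the submitters in a later update. Of 23932 features, 17869 are genes, 17790 of which were found in the Ensembl release 115 annotation of BDGP6, and the 6063 transposon insertions, repeats and extra transcripts were left out.

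Populations were formed within each library. Barcodes with 500 or more genes and at most 10% mitochondrial UMIs were kept (7513, 8169, 15239 and 16123 in the order control 1, Argk1 RNAi 1, control 2, Argk1 RNAi 2), normalised per cell, log-transformed and clustered on 2000 variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0), giving 27, 27, 24 and 29 clusters. A cluster was named when at least 50% of the fixed markers of 1 cell type reached 50 CPM (counts scaled to a common library total) and this share led the next type by 20 percentage points or more. At least 3 of its markers had to reach that level, no other type could have more markers among the cluster's 10 leading genes, and a cluster with a median UMI count under that of the library divided by 3 needed 1 marker among those genes. This naming rule was set after the clusters had been seen, and it left matching clusters named in one library and unnamed in another. Epithelium-like cells numbered 1184, 3095, 9853 and 11016, and unnamed clusters held 5.23%, 13.9%, 24.2% and 16.7% of cells; 26 trachea-like cells in control replicate 1 entered only the alternative over every cluster outside myoblasts. Doublets were scored by the share of simulated doublets among each cell's neighbours and called at 0.8% per 1000 cells (452, 534, 1858 and 2080 cells), and were removed only in the stricter filter and in the epithelium and joined myoblast populations split by roX. Myoblasts were the annotated barcodes. Cells were called roX-low under 200 and roX-high above 400 CPM of roX1 and roX2 together, limits chosen after the data were examined.

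Genes were tested on raw UMIs summed per library and population, with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, the quasi-likelihood test with experiment as a block, two-sided, Benjamini-Hochberg adjustment at 0.05. This leaves 1 residual degree of freedom per gene before dispersions are pooled over genes. The block rests on the batch in the labels; deviations of same-numbered libraries from their group means correlated across genes with 0.335 in myoblasts and 0.299 in epithelium. States were tested where each library had 50 or more cells, state shares with the same test on cell numbers, and the difference between tissues as an interaction with library as a block. DESeq2 1.42.0 (Wald test) and voom of limma 3.58.1 were run beside edgeR in 24 populations, 4 fits each. Groups of 2 libraries allow neither a test of single outlying samples nor other splits of the samples. Libraries were checked for duplication: chi-square per degree of freedom between replicates was 241 for control and 371 for RNAi myoblasts, far above the 1 that pure counting would give. Intervals of shares are exact binomial at 95% and cover counting error only.

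The 38 gene lists were written before the data were examined and tested with camera (preset correlation 0.01, 3 or more members), with an estimated correlation beside it and with fry. The rule for named genes was also set beforehand: in myoblasts the 10 largest rises and falls past the threshold, moving the same way in both experiments and at 20 or more CPM, in other populations 5, filled up to 5 by smallest p, and up to 4 members per list. Cyp6a17 is named by this rule as well; no fitted fold is given for it, since both RNAi libraries are at 0 and a count of 0 allows up to 3.

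The procedure was tested on simulated data with library sizes and dispersions of the real counts and 100 genes changed at each fold. The changed genes all had a mean of 20 CPM or more, so recovery below that level was not measured. Each simulated fold was the same in both experiments, and genes were drawn independently. In the real myoblasts the fold changes had an SD of 0.405 in experiment 1 and 0.173 in experiment 2, with a correlation of -0.0669 at 20 CPM or more. The rates below therefore do not measure recovery in the real data. In myoblasts 90% of 2-fold and 100% of 4-fold changes were recovered with 13 false calls, and without the block 13% and 99%. In epithelium 68% and 100% were recovered with 13 false calls, in DFM 90% and 100% with 12, and in IFM_1 70% and 100% with 5. A simulated shifted list had an adjusted p of 2.4e-07 with the preset and 0.982 with the estimated correlation, so the estimated form had little power at this size. The list members were simulated independently of each other, so the preset was not tested on correlated lists. Alternatives covered the block, scaling, tool, low-count filter, cell filter, thinning to 5000 UMIs, the library total, myoblasts from clustering, equal cells per state, every cluster whose largest marker share is not that of myoblasts (added after the data were examined), the epithelium without clusters whose median UMI count is above 10 times that of the library (added likewise; 1 cluster, in control replicate 1) and leaving out each library, where the fit has no block; a lone library is then assumed to vary like the other group. Figures were drawn with matplotlib 3.10.9.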

Results

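Wing discs of wandering larvae, the last stage before pupariation, were dissociated and profiled by droplet-based 3′ single-cell RNA sequencing in 4 libraries. Per the labels, the pouch had been removed from the discs. In 2 libraries the muscle-lineage driver Mef2-GAL4 expressed a hairpin against Argk1, the fly arginine kinase that moves phosphate between ATP and an arginine store, and in 2 control libraries it expressed a hairpin against mCherry, a fluorescent protein that flies lack. Each group has 1 library from each of 2 experiments, which differ in kit and in the number of cells loaded, so replicate 1 stands for experiment 1 and replicate 2 for experiment 2. The labels describe separate preparations, and nothing in them says how many animals went into each. Every p-value therefore measures at most the spread between these samples, with dispersions pooled over genes. Total counts were 383596409 UMIs in control replicate 1, 304462740 in Argk1 RNAi replicate 1, 349105679 in control replicate 2 and 481419355 in Argk1 RNAi replicate 2. The deposited barcodes numbered 8415, 10104, 20839 and 26031 in the same order. The submitters' annotation covers 11489 of these 65389 barcodes, all of them adult muscle precursors (myoblasts), in 6 states named DFM (direct flight muscle) and IFM_0 to IFM_4 (indirect flight muscle). Annotated myoblasts numbered 4493, 3652, 1315 and 2029 per library, with medians of 25418, 14092, 17244 and 24671 UMIs per cell. They made up 53.4%, 36.1%, 6.31% and 7.79% of the barcodes.

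The first comparison asked whether the targeted gene was lowered in the cells in which the driver is active. Argk1 (listed as Argk, FBgn0000116; BDGP6 chromosome 3L, 9048781 to 9066027, minus strand) fell in myoblasts from 1698 CPM (counts scaled to a common library total) in control replicate 1 to 54.2 in Argk1 RNAi replicate 1, and from 786 in control replicate 2 to 225 in Argk1 RNAi replicate 2. Its log2 fold change was -3.38 ± 0.53 (SE, n = 2 per group; edgeR's quasi-likelihood test, adjusted p 0.0191), with -4.97 in experiment 1 and -1.80 in experiment 2. In the disc epithelium, named here by clustering all barcodes past the cell filter, the levels were 682, 479, 673 and 709 CPM, and the log2 fold change of -0.22 ± 0.24 did not pass the threshold (edgeR's quasi-likelihood test, adjusted p 0.989). The difference between the tissues, tested as an interaction, was -3.14 ± 0.52 on the log2 scale, with an unadjusted p of 0.000516 and an adjusted p of 0.285 by edgeR's quasi-likelihood test over 10491 genes. The paralogs CG5144 and CG4546, which encode related arginine kinases, had 28 and 4 UMIs over all annotated myoblasts, too few for a test of compensation. The fall ranged from -4.49 to -2.46 when each library was left out in turn. Those fits have no block, and without the block all 4 libraries gave -3.15, not past the threshold. The range therefore mixes the library left out with the difference between the experiments.

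Argk1 was also counted per cell, after every cell was thinned to 5000 UMIs. At least 1 Argk1 UMI was found in 88.9% of myoblasts of control replicate 1 (95% exact interval 87.9 to 89.8) and in 16.7% of those of Argk1 RNAi replicate 1 (15.4 to 17.9). In experiment 2 the shares were 66.0% in the control (63.3 to 68.6) and 48.8% with RNAi (46.6 to 51.0). Epithelium, where the gene is expressed too, had 95.7%, 87.3%, 93.3% and 93.8% in the order control and RNAi replicate 1, control and RNAi replicate 2, at medians of 58016, 25350, 12310 and 17850 UMIs per cell before thinning. Without thinning, the myoblast shares were 97.3%, 29.8%, 85.7% and 76.7%, and those of epithelium 99.3%, 97.6%, 89.2% and 93.6%. Cells under 5000 UMIs were left out, from 7 to 86 myoblasts and from 38 to 3003 epithelium cells per library. Free epithelial RNA can add Argk1 UMIs to any droplet, so a share of cells with a UMI is not a share of cells that escaped the hairpin.

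**Figure D1:**
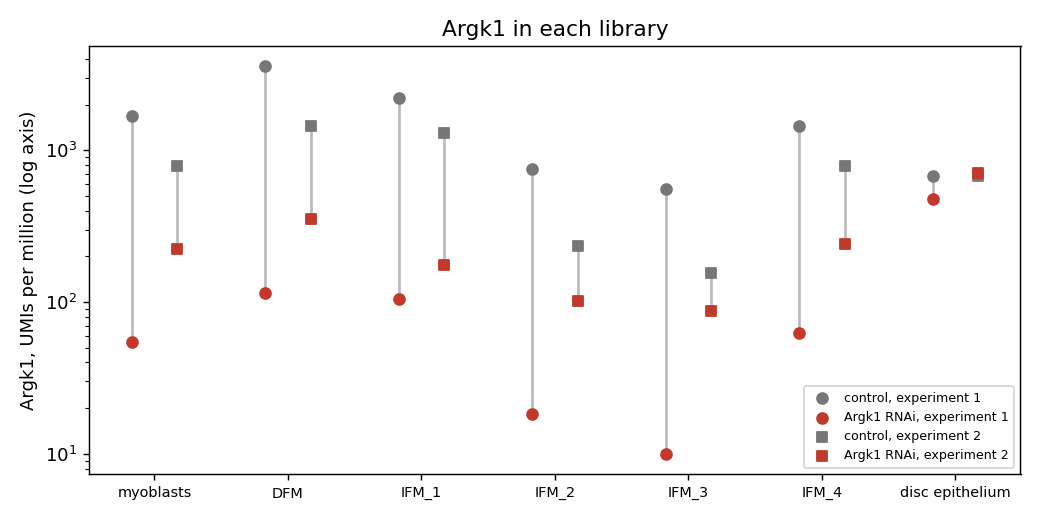
Argk1 level in CPM (log axis) in annotated myoblasts, in the 5 tested myoblast states and in disc epithelium; each point is 1 library, and a line joins the control (grey) and Argk1 RNAi (red) library of 1 experiment. In myoblasts the control libraries sit at 1698 and 786 and the RNAi libraries at 54.2 and 225, while the 4 epithelium values lie between 479 and 709.

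The comparison over all genes asked which other transcripts differ in myoblasts when Argk1 is lowered. The calcium channel gene cac rose from 1.07 and 0.710 CPM in the controls to 6.71 and 5.19, a log2 fold change of 2.74 ± 0.37 (edgeR's quasi-likelihood test, adjusted p 0.0112). The uncharacterised gene CG15093, annotated by homology as a mitochondrial 3-hydroxyisobutyrate dehydrogenase of valine breakdown, fell by 1.37 on the log2 scale (adjusted p 0.0112 by edgeR's quasi-likelihood test), by 1.63 in experiment 1 and by 1.11 in experiment 2. Transcripts of futsch, the microtubule-binding MAP1B homologue, fell from 31.8 and 27.7 to 9.40 and 15.6 CPM, with a log2 fold change of -1.30 ± 0.21 (edgeR's quasi-likelihood test, adjusted p 0.0213). The heat-inducible chaperone gene Hsp70Bb rose (1.44, adjusted p 0.0285 by edgeR's quasi-likelihood test; 0.79 in experiment 1, 2.14 in experiment 2). Its near-identical copies Hsp70Aa (-1.59) and Hsp70Bc (-2.27) fell, both with adjusted p up to 0.0191 (edgeR's quasi-likelihood test), and since such copies share reads their assignment is uncertain.

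Of 8390 genes tested in myoblasts, 5 were higher and 7 lower with Argk1 RNAi at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), Argk1 among the latter; 260 in both directions passed an unadjusted 0.05. The other higher genes were CR40190 (1.02, adjusted p 0.0285 by edgeR's quasi-likelihood test), the pacemaker channel gene Ih (5.62, adjusted p 0.0262) with 5, 178, 1 and 14 UMIs, and CG16957 (4.48, adjusted p 0.0328) with 10, 67, 0 and 88 UMIs. Ih had 3.23 and 0.272 CPM in myoblasts of the RNAi libraries against 46.1 and 2.53 in their epithelium. Epithelial RNA in myoblast droplets was therefore not told apart from a rise of Ih in myoblasts. In experiment 2 Hsp70Aa had 2 UMIs in each library and Hsp70Bc had 0, so these calls rest on experiment 1 alone. DESeq2 called 4 higher and 5 lower, all 9 among the 12, and limma-voom called 12 higher and 14 lower, with the 12 among them. The calls changed whichever library was left out, but those fits have no block. With all 4 libraries the fit without the block called 0 genes. The changes therefore cannot be put down to the library left out. Across the 3979 genes at 20 CPM or more, the fold changes of the 2 experiments had a correlation of -0.0669 (across genes, which are not independent replicates), and their SD was 0.405 in experiment 1 and 0.173 in experiment 2.

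Gene lists fixed beforehand were then compared in myoblasts, first those of energy metabolism, in which arginine kinase acts. Nuclear-encoded respiratory chain genes lay below 0 in 64 of 67 members, with a median log2 fold change of -0.24 that was -0.45 in experiment 1 and -0.06 in experiment 2 (camera, adjusted p 7.4e-11; with an estimated correlation 0.785). Mitochondrial ribosomal proteins fell in median by 0.19 (66 of 72 members below 0; camera, adjusted p 1.3e-07), glycolysis by 0.27 (12 of 14; 5.99e-05) and the TCA cycle by 0.21 (19 of 20; 0.00057). With an estimated correlation each of these had an adjusted p of 0.785. No member of these 4 lists passed over all genes, and adjusted over the list alone only the glycolytic Gapdh1 was lower (-0.80, 0.0469 by edgeR's quasi-likelihood test). Transcripts of the mitochondrial genome (camera, adjusted p 0.438), arginine, proline and polyamine metabolism (0.223) and the adenylate and nucleotide kinases (0.521) were not called. The rotation test fry called the respiratory chain lower (adjusted p 0.00787) and no other list. In roX-low myoblasts, compared below, fry did not call it (adjusted p 0.102). In epithelium its median was -0.34, and fry did not call it there either (adjusted p 0.656).

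Among the remaining lists, heat shock genes had a median of -0.57 in myoblasts (13 of 15 members below 0; camera, adjusted p 7.4e-11), with 1 member higher and 2 lower over all genes and 1 higher and 5 lower adjusted over the list alone. Their median was -1.29 in experiment 1 and 0.00 in experiment 2. Notch targets had a median of -0.44 (camera, adjusted p 0.000293). Adjusted over the list alone, E(spl)malpha-BFM (-1.11), E(spl)m7-HLH (-0.83) and E(spl)m2-BFM (-0.56) were lower at 0.0275 each by edgeR's quasi-likelihood test. The ecdysone response, driven by the moulting steroid, had a median of -0.12 (camera, adjusted p 0.00202) with 3 members lower adjusted over the list alone: ImpE2 (-0.86), ImpE3 (-0.74) and ImpL1 (-3.06). Larval and adult muscle markers, all 6 below 0, had a median of -0.34 (camera, adjusted p 0.0309) that was -1.22 in experiment 1 and 0.40 in experiment 2; the myosin light chain gene Mlc2 was lower adjusted over the list alone (-0.95, 0.00132 by edgeR's quasi-likelihood test). FGF, Hedgehog, Wnt and Dpp signalling (median 0.26, camera, adjusted p 0.00196) and JNK and regeneration (0.15, 0.0412) were called higher with no member past the threshold. With an estimated correlation these 6 lists also had an adjusted p of 0.785. That form missed a truly shifted list in the simulation, so it does not decide on the 10 calls. Nor does the preset, which was simulated on independent genes only. The estimated correlation was 0.31 for heat shock, 0.51 for mitochondrial ribosomal proteins and 0.33 for the TCA cycle, far above the preset. In the rest of the 10 it was at most 0.12 (JNK and regeneration). Of the 10 calls, fry called the respiratory chain alone.

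The sex and dosage compensation list was not called in myoblasts (camera, adjusted p 0.0823), but adjusted over the list alone roX1 (2.78), roX2 (2.43) and msl-2 (1.02), which serve X-chromosome dosage compensation in males, were higher and dsx (-0.44) was lower. The amino acid and ATF4 response was not called (camera, adjusted p 0.911); adjusted over the list alone its translation inhibitor Thor was higher (2.65, 0.01 by edgeR's quasi-likelihood test; 4.48 in experiment 1, 0.63 in experiment 2) and CG11899 lower (-0.80). Of the pouch markers (camera, adjusted p 0.399) only Sp1 was lower adjusted over the list alone (-1.63, 0.00204 by edgeR's quasi-likelihood test), and of the sarcomere genes (0.728) only Mlc2. Other adjusted p-values by camera were 0.243 for indirect and 0.546 for direct flight muscle precursor genes, 0.515 for undifferentiated myoblast genes, 0.309 for myoblast fusion and for apoptosis, and 0.294 for adhesion and matrix. They were 0.376 for S phase, 0.438 for G2 and M phase, 0.467 for cytosolic ribosomal proteins, 0.510 for the unfolded protein response, 0.248 for oxidative stress, 0.279 for antimicrobial peptides, 0.777 for small RNA machinery and 0.873 for transgene marker genes. Lists of other tissues gave 0.467 for disc epithelium, 0.19 for trachea, 0.438 for glia, 0.873 for neural precursors and 0.946 for haemocytes. Mean and median differed in sign for the nucleotide kinases and the transgene markers, and for the ATF4 response both were above 0 while camera's direction was down. The arginine kinase family and fat body lists had fewer than 3 tested members in myoblasts.

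The next comparison asked which myoblast state carries the changes. In DFM cells Thor, the 4E-BP inhibitor of translation that rises when TOR signalling is low, went from 3.07 and 3.83 to 29.6 and 28.7 CPM, a log2 fold change of 3.15 ± 0.28 (edgeR's quasi-likelihood test, adjusted p 2.0e-08). The microtubule-binding futsch fell there from 169 and 164 to 50.2 and 82.7 CPM (-1.37, adjusted p 0.00141 by edgeR's quasi-likelihood test). The Notch targets E(spl)malpha-BFM (-1.53) and E(spl)m7-HLH (-1.36) also fell in DFM, with adjusted p up to 0.029 (edgeR's quasi-likelihood test), mostly in experiment 1 (-2.62 and -2.23 against -0.25 and -0.31). LManII, a lysosomal alpha-mannosidase gene, fell by 1.35 (adjusted p 0.00805). In IFM_1 the axon-guidance gene fend rose (1.81, adjusted p 9.74e-08 by edgeR's quasi-likelihood test) and the POU-domain gene pdm3 fell by 1.36 (adjusted p 0.00224), with the same direction in both experiments. The roX-high share of IFM_1 also rose from control to RNAi in both, from 1.14% to 58.0% and from 8.43% to 60.5%. The agreement of the experiments therefore does not tell Argk1 RNAi from this mix, and roX-low IFM_1 cells were too few to fit.

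Argk1 itself fell in DFM by 3.50 (SE 0.37, adjusted p 7.15e-07 by edgeR's quasi-likelihood test) and in IFM_1 by 3.58 (SE 0.21, adjusted p 9.35e-59). Its log2 fold changes of -3.23, -3.32 and -3.10 in IFM_2, IFM_3 and IFM_4 were of like size but did not pass (edgeR's quasi-likelihood test, adjusted p 0.109, 0.245 and 0.938), so the states were not shown to differ. In the IFM_1 fit roX1 had an SE of 0.26, although it rose by 6.67 in experiment 1 and by 2.52 in experiment 2. The SEs of this fit rest on dispersions pooled over genes, so its very small p-values do not measure a gene's spread between libraries. DFM had 4 genes higher and 20 lower of 6975, and IFM_1 had 21 higher and 24 lower of 6200, among them roX1 (4.51), roX2 (3.69) and pre-rRNA:CR45847 (3.47) as the largest rises, beside CR40190 (1.23) and falls of Hsp68 (-2.12), CG15093 (-1.56) and futsch (-1.44). DESeq2 called 2 higher and 1 lower in DFM, 1 and 2 in IFM_1 and 0 in IFM_2, and limma-voom called 18 and 29, 25 and 27, and 0. In DFM roX1 (1.89), pre-rRNA:CR45847 (1.94) and Hsp70Bb (1.59) were higher as well. IFM_2 had 2 higher (cac 3.13 and CR44268 2.32) and 4 lower of 6812 genes, namely CG15093 (-1.40) and Hsp70Aa, Hsp70Ab and Hsp70Bc. IFM_3 had 0 higher and 4 lower of 6748 genes, E(spl)malpha-BFM (-2.27, adjusted p 0.0136 by edgeR's quasi-likelihood test) and the same 3 Hsp70 copies; 93 and 119 passed an unadjusted 0.05, DESeq2 called 0 and limma-voom 0 higher and 5 lower. IFM_4 had 0 calls of 7846 genes by edgeR's quasi-likelihood test (118 higher and 161 lower at an unadjusted 0.05), 0 by limma-voom and 2 higher and 2 lower by DESeq2; cac (2.37) and CG15093 (-1.44) had the smallest p. IFM_0 was not tested, with 25 cells in control replicate 2. The IFM_1 sums hold 352, 50, 83 and 119 cells, and roX-high cells make up 1.14%, 58.0%, 8.43% and 60.5% of them.

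Another comparison asked whether the states make up other shares of the annotated myoblasts. The DFM share was level, at 14.7% and 14.7% in the control and RNAi library of experiment 1 and 15.2% and 15.1% in experiment 2 (exact 95% intervals between 13.3 and 17.3). IFM_3 went from 6.68% to 25.1% in experiment 1 and from 11.9% to 7.89% in experiment 2, opposite directions whose exact intervals do not overlap within either experiment. IFM_1 went from 7.83% to 1.37% and from 6.31% to 5.87%, IFM_2 from 9.33% to 11.8% and from 11.1% to 12.1%, and IFM_0 from 3.49% to 1.94% and from 1.90% to 2.56%. IFM_4, the most abundant state, went from 58.0% to 45.1% and from 53.6% to 56.5%. None of the 6 shares passed (edgeR's quasi-likelihood test, adjusted p from 0.902 to 0.933; unadjusted p from 0.171). Without Argk1 RNAi replicate 2, IFM_1 was lower (-2.38) and IFM_3 higher (1.46), both at an adjusted p of 0.0268 (edgeR's quasi-likelihood test). The shares are of annotated cells, and annotated cells are a varying part of each library.

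**Figure D2:**
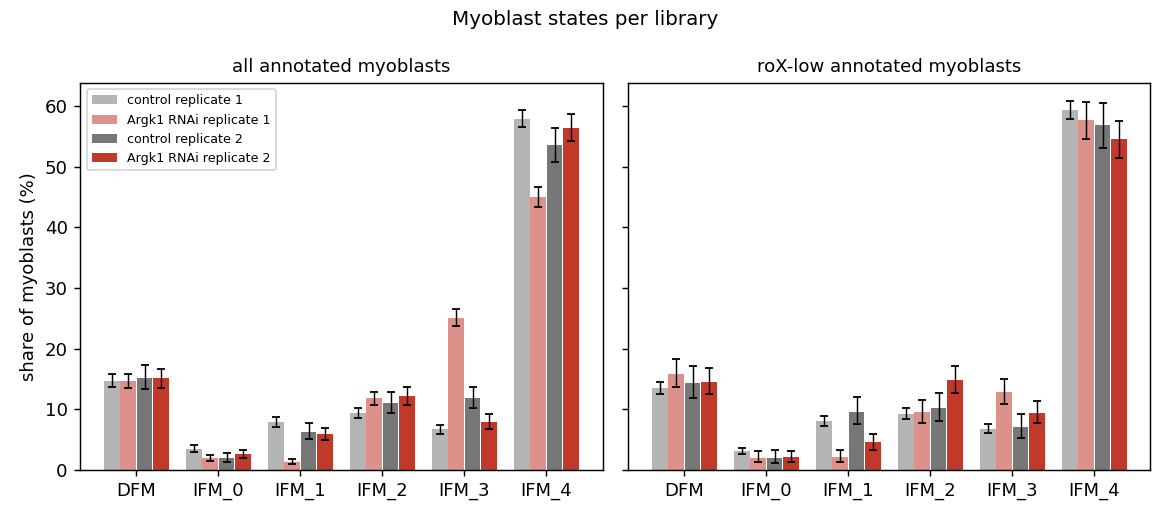
Share of each myoblast state per library in percent, over all annotated myoblasts (left) and over roX-low annotated myoblasts (right); bars are single libraries and whiskers their exact 95% binomial intervals. Over all myoblasts IFM_3 stands at 25.1% in Argk1 RNAi replicate 1 against 6.68% to 11.9% in the other 3 libraries, and over roX-low cells at 12.8% against 6.82% to 9.35%.

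The same contrast was measured in disc epithelium, in which Mef2-GAL4 is not known to drive. LManII fell from 29.2 and 38.6 to 3.46 and 8.94 CPM, a log2 fold change of -2.59 ± 0.27 (edgeR's quasi-likelihood test, adjusted p 9.47e-05). Ih rose here too (3.69, adjusted p 1.94e-05 by edgeR's quasi-likelihood test), as did CR44268 (2.71), asRNA:CR46487 (3.80) and CG43646 (3.41).

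For other calls in epithelium, the clusters led by the genes themselves were kept by the naming in some libraries and left unnamed in others. Cells led by Cpr49Ac, Idgf4 and CG4382 were kept in control replicate 2 (438 cells) but left unnamed in Argk1 RNAi replicates 1 (225) and 2 (315) and in control replicate 1 (27), while a cluster led by Cpr49Ag (93 cells) was kept in control replicate 1 and one with Cpr49Ag (74) left unnamed in Argk1 RNAi replicate 2. The cuticle protein genes Cpr49Ag (-6.12) and Cpr49Ac (-2.29) and the chitinase-like growth factor gene Idgf4 (-1.05) fell, with adjusted p up to 0.0416 (edgeR's quasi-likelihood test). Cells led by dve, a homeobox gene of the proximal wing and pouch, were kept in control replicate 1 (88 cells) and in Argk1 RNAi replicates 1 (478) and 2 (1297) but left unnamed in control replicate 2 (742), and dve rose by 1.71 (adjusted p 0.0431 by edgeR's quasi-likelihood test), together with the pouch markers. An alternative added after the data were examined took every cluster outside myoblasts, named or not (1395, 3935, 13319 and 13328 cells). In it Idgf4 (-0.27) and Cpr49Ac (-0.80) were not called, while Cpr49Ag and dve stayed past the threshold (edgeR's quasi-likelihood test, adjusted p 4.06e-17 and 0.000513), with -6.06 in experiment 1 and -1.71 in experiment 2 for Cpr49Ag and 2.66 and -0.21 for dve. The SEs of Cpr49Ag and dve in this fit were 0.41 and 0.25, small beside the gap between the experiments. Their p-values therefore do not measure that gap. LManII (-2.55), Ih (3.67), CR44268 (2.66), asRNA:CR46487 (3.77) and CG43646 (3.45) moved as before. This fit called 43 genes higher and 73 lower of 10619, with 24 of the 28 below among them, DESeq2 8 and 36, limma-voom 30 and 55, and edgeR without the block 0.

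In control replicate 1 that Cpr49Ag-led cluster of 93 barcodes has a median of 656860 UMIs and holds 29.2% of the epithelium UMIs in 7.85% of the epithelium barcodes. With the cluster left out, an alternative also added after the data were examined, only Ih (3.66) and Cpr49Ac (-2.24) were called of 10458 genes (edgeR's quasi-likelihood test, adjusted p 0.0497 each; 109 higher and 276 lower at an unadjusted 0.05). DESeq2 called 12 higher and 51 lower in this population, limma-voom 1 and 2, and edgeR without the block 0. Cpr49Ag then changed by -0.64 in experiment 1 and -5.94 in experiment 2. LManII (-2.63), CR44268 (2.91), asRNA:CR46487 (3.85), CG43646 (3.53), Idgf4 (-0.95) and dve (1.62) kept their sizes without passing (edgeR's quasi-likelihood test, adjusted p from 0.0744 to 0.719).

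Of 10412 genes tested in epithelium, 8 were higher and 20 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg), and 140 and 350 passed an unadjusted 0.05. DESeq2 called 15 and 53 and limma-voom 19 and 46, sharing 22 and 28 of the 28 genes. The cytochrome P450 gene Cyp6a17 had 110 and 273 UMIs in epithelium of the controls and 0 in both Argk1 RNAi libraries; over all barcodes it had 145 and 400 against 0 and 0, where a count of 0 allows up to 3. The calls changed whichever library was left out, but those fits have no block. With all 4 libraries the fit without the block called 1 gene, which was among the 28. These changes therefore cannot be put down to the library left out.

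The lists were tested in epithelium too, where camera called 15 at the preset correlation, none with an estimated correlation (smallest adjusted p 0.711), and fry called 0 of 37. Heat shock (median -0.83; camera, adjusted p 2.69e-11), the respiratory chain (-0.34; 4.26e-11), mitochondrial ribosomal proteins (-0.29; 4.26e-11), glycolysis (-0.26; 0.000451), the TCA cycle (-0.19; 0.0128) and Notch targets (-0.18; 0.00804) were lower. Of the clusters led by the Notch target E(spl)mgamma-HLH, those of control replicate 1 (57 cells) and control replicate 2 (362) were kept, while in each RNAi library one was kept (87 and 158) and one left unnamed (101 and 267). Oxidative stress (-0.28; camera, adjusted p 0.000194), the ATF4 response (-0.31; 0.0393) and the ecdysone response (-0.01; 0.0393) were lower as well. The pouch markers, all 8 above 0, had a median of 0.96 (camera, adjusted p 4.26e-11) that was 1.81 in experiment 1 and 0.11 in experiment 2, with 6 higher adjusted over the list alone, pdm2 (1.49), nub (1.10) and rn (1.06) among them; the labels say that the pouch was removed. FGF, Hedgehog, Wnt and Dpp signalling (0.28; camera, adjusted p 0.000238), disc epithelium markers (0.16; 0.000861), S phase (0.18; 0.0122), G2 and M phase (0.21; 0.0122) and the sex list (0.12; 0.0379) were higher. In every cluster outside myoblasts, named or not, Notch targets (median -0.08; camera, adjusted p 0.21) and the ATF4 response (0.0718) were not called, and the pouch markers had a median of 1.81 in experiment 1 and -0.06 in experiment 2. With the deepest cluster of control replicate 1 left out, the sex list (camera, adjusted p 0.201) and the ecdysone response (0.0742) were not called. Fat body markers were tested in epithelium only (camera, adjusted p 0.966).

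Whether a change differs between the tissues was tested as an interaction over 10491 genes. LManII fell less in myoblasts than in epithelium (difference 1.64 ± 0.13, adjusted p 0.0286 by edgeR's quasi-likelihood test), and the sugar transporter gene Tret1-1 (2.17), the capsid-like synaptic gene Arc1 (1.27) and Hsp70Bb (1.83) also differed toward myoblasts, with adjusted p up to 0.0488. The difference for dve was -1.70 and for CR44334 -1.33, both with more of a rise in epithelium, where the clusters led by these genes were kept or left out unevenly. These 4 and 2 genes were the calls by edgeR's quasi-likelihood test, 239 and 193 passed an unadjusted 0.05, and limma-voom called 0. With every cluster outside myoblasts as the epithelium, only LManII (1.60) and Hsp70Bb (1.74) were called (edgeR's quasi-likelihood test, adjusted p 0.04), while dve (-1.25) and CR44334 (-0.98) were not. With the deepest cluster of control replicate 1 left out, no gene was called (LManII 1.67, adjusted p 0.34 by edgeR's quasi-likelihood test).

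The libraries also differ in their mix of male and female cells, read from the male-specific dosage compensation RNAs roX1 and roX2. The roX-high share of annotated myoblasts was 3.27% in control replicate 1 and 72.2% in Argk1 RNAi replicate 1, against 43.4% and 47.4% in experiment 2. In epithelium it was 26.6% and 77.6% in experiment 1 and 68.7% and 46.6% in experiment 2. The rises of roX1, roX2, msl-2 and pre-rRNA:CR45847 in myoblasts and in their states move with this mix.

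A comparison added after the data were examined therefore used roX-low annotated myoblasts alone, 4340, 997, 698 and 1037 cells. The BTB zinc-finger gene chinmo, which keeps progenitors in an early temporal identity, rose in them by 1.21 (adjusted p 5.71e-05 by edgeR's quasi-likelihood test), by 1.28 and 1.13 in the 2 experiments. The ecdysone-induced ImpE2 (-0.97, adjusted p 0.000857 by edgeR's quasi-likelihood test) and ImpE3 (-0.77, 0.0226) fell, while the ecdysone list had 8 members above 0 and 10 below, a median of -0.04, and 1 higher and 5 lower adjusted over the list alone (camera, adjusted p 0.0202; with an estimated correlation 0.734). The small heat shock gene Hsp23 fell by 0.63 (0.0293), and the zinc-finger gene Sp1 fell by 1.67 (8.05e-06). The transcription factor genes fru (0.73) and ab (0.91) and the signalling genes fj (0.74) and fog (0.64) rose, with adjusted p up to 0.0183. Argk1 changed by -4.09 in experiment 1 and -2.79 in experiment 2, -3.43 in all (adjusted p 5.59e-07 by edgeR's quasi-likelihood test). In all, 22 genes were higher and 20 lower of 7650 (324 and 407 at an unadjusted 0.05; DESeq2 12 and 12, limma-voom 53 and 46, edgeR without the block 0 and 0), 10 of them among the 12 called over all myoblasts, and the fold changes of the 2 experiments had a correlation of 0.0961 over all 7650 genes and 0.335 over the 3971 at 20 CPM or more (across genes, which are not independent replicates). In roX-high myoblasts edgeR, DESeq2 and limma-voom each called 0 of 7458 genes, with 29 and 74 at an unadjusted 0.05 by edgeR's quasi-likelihood test; control replicate 1 holds 147 such cells. Argk1 went in them from 5237 to 36.1 CPM in experiment 1 and from 338 to 303 in experiment 2, log2 fold changes of -7.17 and -0.16 with a mean of -3.67 ± 2.53 (edgeR's quasi-likelihood test, adjusted p 1.00). Between the experiments their fold changes had a correlation of -0.437 at 20 CPM or more (across genes, which are not independent replicates).

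Over roX-low myoblasts IFM_3 made up 6.82% and 12.8% in the control and RNAi library of experiment 1 and 7.02% and 9.35% in experiment 2, where the exact intervals overlap (5.24 to 9.18 and 7.65 to 11.3). Over roX-high myoblasts it made up 2.72% and 29.9% in experiment 1 and 18.4% and 6.45% in experiment 2, opposite directions, but the 147 roX-high cells annotated in control replicate 1 are 52.4% DFM and 15.6% IFM_4, against 14.2% to 15.5% and 40.3% to 58.5% in the other 3 libraries, so experiment 1 compares unlike selections. In roX-low cells IFM_1 made up 8.02% and 2.11% in experiment 1 and 9.60% and 4.53% in experiment 2, a log2 fold change of -1.47 ± 0.63 (edgeR's quasi-likelihood test, unadjusted p 0.0581, adjusted p 0.348). Of 35 lists tested in roX-low myoblasts, camera called 2 higher and 9 lower and none with an estimated correlation (smallest adjusted p 0.734). The respiratory chain had a median of -0.22, -0.33 in experiment 1 and -0.07 in experiment 2. The rotation test fry called 0 lists higher and 0 lower, with an adjusted p of 0.102 for the respiratory chain.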

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

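The roX thresholds, the use of every cluster outside myoblasts, the epithelium without its deepest cluster and the tests by genetic background, for Ih, for Cyp6a17 and against the median of the myoblast markers were chosen only after the result was seen; the other tests were set before.

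A test of the difference between tissues singled out 4 genes higher and 2 lower in myoblasts relative to epithelium (10491 genes; limma-voom 0), and with every cluster outside myoblasts as the epithelium 2 higher and 0 lower, and with the deepest cluster of control replicate 1 left out 0 and 0; matching clusters were named epithelium in some libraries and left unnamed in others. The same test gave -3.14 for Argk1, with an adjusted p of 0.285 (edgeR's quasi-likelihood test), so it did not pass over all genes. A signal in data outside the annotation was the roX-high share of 48.4% among myoblast-like cells without an annotation in control replicate 1, against 3.27% among its annotated myoblasts.

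The 2 experiments gave different pictures: the IFM_3 share was higher with RNAi in one and lower in the other, and the fold changes of myoblasts had a correlation of -0.0669 across genes at 20 CPM or more. Depth between paired libraries was tested by thinning every cell to 5000 UMIs. The correlation was then -0.137, so equal UMI counts per cell did not bring the fold changes together. Summed counts were already scaled for depth, and thinning does not touch the state shares or which cells were annotated, so the test does not decide on other traits that go with depth. The mix of roX-high and roX-low cells may account for part of the difference between the experiments: over roX-low cells alone the IFM_3 share was higher in experiment 2 as well, by 2.33 percentage points, although within overlapping intervals, and the correlation was 0.335 (0.0961 over all genes). Over roX-high cells alone the share still moved in opposite directions (2.72% to 29.9% and 18.4% to 6.45%) and the correlation was -0.437, but the 147 such cells annotated in control replicate 1 are 52.4% DFM against 14.2% to 15.5% elsewhere, so these values do not settle whether the mix accounts for all of it. The kit, the cells loaded and the larvae of each experiment stay open, and an effect of Argk1 that differs between the sexes was not tested.

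Of 11 genes called in myoblasts besides Argk1, 10 were tested in epithelium, 9 moved in the same direction and 4 were called there too (10 of 11 and 4 over every cluster outside myoblasts, 10 of 11 and only Ih with the deepest cluster left out), in tissues that share the same 4 libraries. Against RNA carried over from myoblasts stands that the median ratio of their epithelium to myoblast level is 36.2 times that of the 9 myoblast markers, and that Ih is 9.46 times or more as high in epithelium as in myoblasts of the same RNAi libraries. The bound set beforehand, the highest marker, gave 0.477 and decides nothing, since that marker (kirre) is itself expressed in epithelium at a ratio of 1.13. The reverse, epithelial RNA carried into myoblast droplets, was not tested and stays open for Ih. A difference of genetic background between the crosses may explain part: the median change in epithelium was 0.628 of that in myoblasts (0.65 with the deepest cluster left out), and Cyp6a17, which is deleted in some fly strains, had 0 UMIs over all barcodes of both RNAi libraries. That median does not speak for every gene. The share was 0.217 for CG15093, 0.281 for cac, 0.184 for futsch and -0.24 for Hsp70Bb, none of them called in epithelium. For the remaining tested genes it ran from 0.599 (CR40190) to 2.03 (Hsp70Aa). Larval stage, the 2 hairpins and a signal from myoblasts to epithelium stay open, as the design confounds them with the groups.

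In control replicate 1 the annotation holds 17.6% of the roX-high but 85.6% of the roX-low myoblasts, while in the other 3 libraries the shares lie between 76.9% and 93.6%. The UMI, gene and mitochondrial limits of the annotated cells do not explain this, because 90.8% of the roX-high myoblast-like cells without an annotation lie inside the range of the annotated ones. No other step of the annotation was tested, and no biological explanation was tested. The comparison over all annotated myoblasts of experiment 1 therefore sets mostly roX-low control cells against mostly roX-high RNAi cells.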

How the results depend on the processing

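The comparisons within roX-low and roX-high cells and over every cluster outside myoblasts, and leaving out the deepest epithelium cluster of control replicate 1, were chosen only after the result was seen, and the other alternatives, like the block, the tests and the gene lists, were set before the data were examined. The rule that names clusters, on which the epithelium and the myoblasts from clustering rest, was set after the clusters were seen. With 2 libraries per group and 1 residual degree of freedom, the number of calls swings with the choices below, so the calls are few and unstable. Most directions of the named genes and lists held. The alternatives refit the same 4 libraries, and many named genes were picked for their small p or for moving the same way in both experiments. Kept directions therefore do not measure agreement of the experiments, whose fold changes in myoblasts had a correlation of -0.0669 at 20 CPM or more. Of the named genes and lists in myoblasts, 2720 values under the alternatives kept their direction and their side of the threshold, 136 lost it, 59 gained it and 6 reversed; in epithelium these were 2368, 131, 96 and 1. Where a call was lost or a direction reversed below, the cause was not tested.

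Argk1 level kept its direction in myoblasts under every alternative, with adjusted p from 8.27e-36 to 1.00 (edgeR's quasi-likelihood test unless named). Its value without the replicate block, which pairs the libraries, was -3.15; it was -3.38 with size factors, -3.39 by DESeq2, -3.36 at 20 CPM or more, -3.38 with the stricter cell filter, -3.39 in thinned cells, -3.37 in myoblasts from clustering and -3.23 in state-balanced cells, each no longer past the threshold. In roX-high cells it was -3.67 (-7.17 in experiment 1, -0.16 in experiment 2), and -3.20 with cells lacking an annotation (-6.10 and -0.30), also not past it. Leaving out 1 library gave -4.49 to -2.46.

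The numbers of genes higher and lower in myoblasts were 0 and 0 without the replicate block, with size factors, with the stricter cell filter, in thinned cells, in state-balanced cells and in roX-high cells with or without an annotation. They were 12 and 14 by limma-voom, 33 and 33 with no filter on low counts, 0 and 1 at 20 CPM or more, 13 and 18 without mitochondrial genome and ribosomal protein genes, and 2 and 3 in myoblasts from clustering. In roX-low cells they were 22 and 20, and 18 and 19 with cells lacking an annotation. Leaving out 1 library gave 0 to 7 higher and 0 to 7 lower.

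In epithelium the numbers were 0 and 1 without the replicate block, 14 and 35 with size factors, 15 and 53 by DESeq2, 19 and 46 by limma-voom, 56 and 90 with no filter, 16 and 50 in thinned cells, 50 and 93 without mitochondrial genome and ribosomal protein genes, 43 and 73 over every cluster outside myoblasts, named or not, 1 and 1 with the deepest cluster left out, 59 and 122 in roX-low cells and 0 and 0 in roX-high cells. With the stricter cell filter 13 were higher. Leaving out 1 library gave 0 to 18 higher and 0 to 21 lower.

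By state, the fit without the replicate block gave 1 higher and 0 lower in DFM, 0 and 1 in IFM_1, 0 and 0 in IFM_2 and 0 lower in IFM_3. In roX-low cells the numbers were 18 and 31 in DFM, 28 and 20 in IFM_2 and 55 and 68 in IFM_4, while IFM_1 and IFM_3 had fewer than 50 such cells in a library and were not run. Leaving out 1 library gave 0 to 5 higher and 0 to 12 lower in DFM, 0 to 3 and 0 to 8 in IFM_1, 1 to 17 and 0 to 25 in IFM_2, 0 to 3 lower in IFM_3, and 0 to 3 and 0 to 1 in IFM_4. The state shares ranged from -2.38 to -0.28 for IFM_1 and from -0.21 to 1.46 for IFM_3, past the threshold only without Argk1 RNAi replicate 2.

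The difference between the tissues gave 0 higher and 0 lower by limma-voom and without the block for population by experiment, 2 and 0 with every cluster outside myoblasts as the epithelium, and 0 and 0 with the deepest cluster left out. Lists in myoblasts numbered 0 higher and 0 lower with an estimated correlation and 0 and 1 by fry, and 0 to 8 higher and 3 to 7 lower when 1 library was left out; in epithelium both forms gave 0 and 0, and camera gave 7 and 7 over every cluster outside myoblasts and 5 and 9 with the deepest cluster left out.

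Every reversal came without control replicate 1, whose value is the upper end of each gene's range below when 1 library is left out. That fit has no block and sets Argk1 RNAi replicate 1 against a control of the other experiment. A reversal in it is therefore not told apart from a difference between the experiments. In myoblasts Hsp70Aa ranged from -9.45 to 6.69 and Hsp70Bc from -12.75 to 9.89, and in epithelium Hsp70Aa ranged from -8.92 to 1.81. In DFM E(spl)malpha-BFM ranged from -2.86 to 0.035 and in IFM_1 Hsp68 from -4.26 to 0.66. In IFM_2 Hsp70Bc ranged from -9.77 to 5.69, Hsp70Aa from -11.00 to 8.26 and Hsp70Ab from -9.46 to 5.85, and in IFM_3 Hsp70Aa from -6.95 to 8.46 and Hsp70Ab from -8.64 to 6.44. The Hsp70 copies Aa, Ab and Bc are at or near 0 UMIs in the myoblasts of experiment 2, so these fitted sizes have no meaning as folds. Among lists in myoblasts (camera of limma), 4 reversed without control replicate 1: heat shock at an adjusted p of 0.0841 (1.22e-07 to 0.202 over the libraries left out), FGF, Hedgehog, Wnt and Dpp signalling at 0.618 (7.02e-07 to 0.618), disc epithelium markers at 8.92e-08 (8.92e-08 to 0.495) and larval and adult muscle markers at 0.932 (2.61e-05 to 0.932).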

Other observations

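The comparison of roX-high with roX-low cells, the comparison within roX-low cells, with or without the deepest epithelium cluster, and the test of a change shared by both tissues were chosen only after the result was seen; the test of X-linked dosage was set before its result.

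Within the 4 libraries, roX-high and roX-low myoblasts (annotated or myoblast-like) differed in the genes of the sex pathway. msl-2, the male dosage compensation factor, was higher in roX-high cells by 2.21 (adjusted p 0.000145), and tra (-0.98, 0.000291) and Sxl (-0.86, 0.00549), which direct female development, were lower, all by edgeR's quasi-likelihood test and in the same direction in 4 of 4 libraries. Of 7748 genes 36 were higher and 85 lower in roX-high cells, 92 of them X-linked and 27 autosomal. Among the tested genes 1378 were X-linked and 6236 autosomal, so the calls were mostly X-linked though the tested genes were not. The ribosomal RNA precursor CR45847 was higher by 6.27, and the calcineurin subunit gene CanB2 was lower by 0.98. In epithelium 19 were higher and 32 lower of 9448 genes, 43 of them X-linked, where 1611 of the tested genes were X-linked. A large general difference of X-linked dosage was tested as a hypothesis and was not borne out. The median of X-linked genes minus that of autosomal genes was -0.10 on the log2 scale in myoblasts, with interquartile ranges of 0.235 and 0.142. A smaller shift over the X chromosome was not excluded.

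In roX-low cells 41 genes besides Argk1 were called in myoblasts. Of the 40 also tested in roX-low epithelium, 33 moved in the same direction and 14 were called in it, with a median change 0.548 of that in myoblasts (quartiles 0.20 to 0.961). Over all 9368 genes tested in roX-low epithelium, 59 were called higher and 122 lower (edgeR's quasi-likelihood test). Both tissues come from the same 4 libraries, and the share of all genes that moved in the same direction was not computed. The deepest epithelium cluster of control replicate 1 holds 77 roX-low cells, and without it 33 of 39 moved in the same direction and 16 were called, with a median of 0.538. A difference shared by both tissues, such as larval stage or genetic background, may therefore underlie part of these calls, for example fru (0.73 in myoblasts, 1.21 in epithelium), Sap-r (-0.80 and -0.83), both called in epithelium too, and the ecdysone-induced ImpE3 (-0.77 and -0.76), whose epithelium change passed only with the deepest cluster left out (adjusted p 0.123 with it, 0.0297 without, by edgeR's quasi-likelihood test). For others the 2 experiments moved in opposite directions in epithelium, so that no common change could be read there: Sp1 (-1.67 in myoblasts; -0.47 and 0.22 in epithelium, SE 0.59), chinmo (1.21; 0.89 and -0.44) and Thor (1.59; 0.66 and -0.93). MFS3 (1.02 in myoblasts, -0.20 and -0.23 in epithelium, SE 0.21) and Fili (-0.78, then 0.79 and 0.03, SE 0.24) went the other way in epithelium in both experiments. Neither was called in epithelium. Whether the changes of these genes differ between the tissues was not tested within roX-low cells. Larvae of both genotypes staged by hour, and the Argk1 hairpin without the driver, would tell stage, background and Argk1 apart.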
